A study of Mus musculus with 182 samples.

How the data were processed

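Liver RNA was extracted with the PureLink RNA Mini Kit and libraries were made with the TruSeq stranded mRNA kit. Per the submitters' processing notes, reads were aligned to the mouse genome GRCm39 with STAR 2.7.11b and counted per gene with featureCounts 2.0.6. The authors deposited raw integer counts of 14716 genes in 182 libraries, named by Ensembl gene identifiers. The annotation release and the strand setting used for counting were not given. Every deposited gene had at least 10 counts in at least 37 libraries, 20.3% of them, so genes below such a floor were absent from the table. Ren1, a gene fixed for naming in advance, was not in the table.

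Gene symbols came from GENCODE M21, which is built on GRCm38, and were matched by identifier for 14625 of 14716 genes. The other 91 kept their identifiers. The same annotation supplied membership of the X and Y chromosomes, and no coordinates were used. Counts had a median total of 17.1 M per library.

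Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test without robust dispersion, on trimmed-mean-of-M-values factors, after filterByExpr, which kept all 14716 genes. A single fit over 182 libraries held a coefficient for each of 42 groups and additive terms for cohort and site, 46 columns in all, leaving 136 residual degrees of freedom. The median biological coefficient of variation was 0.303. Effects of compounds given to both sexes were the mean of the female and the male effect. P values were adjusted by the method of Benjamini and Hochberg over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Standard errors of log2 differences were derived from the F statistic, and CPM values on a log2 scale used a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 (limma-trend) were run on the same design.

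Gene lists were fixed in advance, and the 48 lists with at least 4 measured genes were tested with camera on log2 CPM at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Scores were tested by permuting labels within sex and cohort, exactly or with 100000 resamples.

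Genes were named by a rule set in advance. In the main comparisons (age in each sex, sex in old controls, Cana together and in each sex, RaAc9, RaAc16, Rapa_20hi, Est_16 and Est_20) up to 8 called genes per direction with the largest log2 change were eligible, and up to 3 in the others. Each needed a mean of at least 1 CPM, an established symbol and every treated or young library on the same side of the control mean of its sex after removal of cohort and site. Up to 4 members with the lowest p were eligible per list, and 16 measured genes were fixed by name beside those of the sex chromosomes.

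Recovery was measured in simulated counts with the library sizes and design of the data and with dispersions estimated from them. Apart from the planted changes, every library had the same gene means, and genes varied independently. Effects of sex, cohort and site and outlying libraries were not simulated, so recovery and false calls in the real data may be worse. For the mean effect of RaAc9 over both sexes, 75 of 100 genes changed by a factor of 2 and 97 of 100 changed by a factor of 4 were recovered, with 10 false calls among 182. For age in females, 75 of 100 and 98 of 100 were recovered, with 11 false calls among 184.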

Results

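PolyA RNA from the liver of UM-HET3 mice, a genetically mixed stock bred for ageing studies, was sequenced from 88 females and 94 males, in 1 library per animal and 42 groups. In each sex there were 24 old controls, 6 young controls aged 4 to 6 months and 7 old mice fed canagliflozin (Cana). All 18 compounds fed to both sexes, canagliflozin aside, had 3 libraries per sex, and 17-alpha-estradiol started at 16 months (Est_16) or 20 months (Est_20) had 3 male libraries each. Old mice were 22 months old at sampling, except that 5 of the 6 captopril mice were 23 months old. The animals came from cohorts labelled C2015, C2016 and C2017 and from 3 sites (JL, UM and UT). Old controls numbered 6, 10 and 8 per sex in these cohorts, and compounds of a cohort shared its controls, so their effects were not independent of each other. Young controls came from UM (4 per sex) and JL (2 per sex), in C2016 and C2017 only. The deposited counts covered 14716 genes and summed to between 11708210 and 45205790 per library.

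Genes of the sex chromosomes matched the sex label of every library. Xist, which silences an X chromosome in females, ranged from 161 to 1090 CPM (counts scaled to a common library total) in females and from 0 to 0.924 CPM in males. Among Y-linked genes, Ddx3y ranged from 8.98 to 82.4 CPM in males and reached at most 0.171 CPM in females. Uty was at least 2.45 CPM, Kdm5d at least 6.9 CPM and Eif2s3y at least 33.2 CPM in every male, and at most 0.09, 0.342 and 0.171 CPM in any female. In 7 libraries, the residuals of the linear model spread more widely than a limit of 0.698 (SD, log2), set from the median of 0.408 over all libraries. They were old female control 20 (0.8), female NR 3 (0.942), male BD 1 (0.754), male Cana 7 (0.756), male GGA 2 (0.856) and young male controls 1 (0.727) and 2 (0.861). Several of them differed from their groups in whole gene classes. Saa1, an acute-phase protein, reached 10800 CPM in female control 20, 4200 CPM in female NR 3 and 15500 CPM in male GGA 2. Young male 2 had 461 CPM of the bile duct keratin Krt19 and 167 CPM of smooth muscle actin Acta2, against at most 4.84 and 5.33 CPM in the other 5 young males.

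Old and young controls were compared in each sex to find what ageing changed in the liver. In females, 10 genes fell and 8 rose with age, and several of those that fell are made mainly in male liver. Slco1a1 (ENSMUSG00000041698), an uptake transporter of bile acids and steroids, fell by 3.71 log2 units (SE 0.59, adjusted p 4.93e-05) from 66.4 ± 68.9 CPM in 6 young females to 8.37 ± 26.8 CPM (SD) in 24 old ones. Hsd3b5, a steroid reductase, changed by -3.50 (SE 0.59), the urinary protein genes Mup7 and Mup3 by -4.65 (SE 0.79) and -1.70 (SE 0.40), the sulfotransferase Sult5a1 by -2.94 (SE 0.54), Cyp2d9 by -1.92 (SE 0.33) and Mtg1, of mitochondrial ribosomes, by -0.40 (SE 0.09). The largest rise was that of Adcy1, an adenylyl cyclase, at 4.10 log2 units (SE 0.93, adjusted p 0.0256), from 2.16 ± 2.69 to 42.6 ± 40.9 CPM. Nxpe5 rose by 3.06 (SE 0.68), Fitm1, which helps to form lipid droplets, by 2.41 (SE 0.56), and the transcription factor genes Dmrta1 and Tcf4 by 1.60 (SE 0.34) and 0.69 (SE 0.17). For each of these genes except Mup7, all 6 young females lay on the same side of the mean of the old controls. By edgeR's quasi-likelihood test, 18 genes passed an adjusted p of 0.05 and 1555 an unadjusted one, and the count moved between 1 (without young female 3) and 32 (without young female 2) when single young females were left out, and was 22, 29 and 41 without replicate 1, 2 or 3 of every group of 3. Reads of Mup genes can be shared among near-identical copies, so their separate values are uncertain.

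Of 48 gene lists fixed before the data were examined, nuclear oxidative phosphorylation genes had the lowest adjusted p in ageing females, at 1.35e-16 (0.355 with an estimated correlation), with a median of -0.246 and no member passing over all genes or adjusted over the list alone. Male-biased liver genes came next by p. Of their 34 members, 5 fell over all genes and 9 with p values adjusted over the list alone, with a median of -0.599 log2 units (adjusted p 4.32e-10 with a preset correlation among genes, 0.355 with an estimated correlation). Markers of B and plasma cells had a median of 1.26. None of their 23 genes passed over all genes by edgeR or limma-trend and 2 did by DESeq2, 5 passed adjusted over the list alone, and the adjusted p was 2.12e-09 with the preset and 0.236 with an estimated correlation. The antibody genes Ighm and Igha had log2 differences of 1.5 (SE 0.54, adjusted p 0.332) and 2.63 (SE 0.89, adjusted p 0.286, 0.0423 by DESeq2). Genes of bile acid synthesis and transport had a median of -0.258. Over all genes 1 of their 21 members fell and adjusted over the list alone 2 did, at an adjusted p of 1.18e-05 (0.355 with an estimated correlation). Cyp27a1, an enzyme of bile acid synthesis, differed by -0.44 (SE 0.15, adjusted p 0.253). In none of these lists did the shift with age pass with an estimated correlation.

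In males, 192 genes rose and 763 fell with age. Dmrta1 rose by 2.56 log2 units (SE 0.37, adjusted p 3.47e-08) and Nxpe5 by 2.71 (SE 0.61, adjusted p 0.00104), so both rose in each sex. Apba2, an adaptor protein, rose by 3.59 (SE 0.57, adjusted p 7.54e-07), Hao2, an oxidase of the peroxisome, by 3.54 (SE 0.78), Grid1 by 2.50 (SE 0.53), Nat8f7 by 2.07 (SE 0.64) and the female-biased Cyp2b9 by 3.52 (SE 0.92, adjusted p 0.00632). Without the 7 libraries with a wide spread, Cyp2b9 kept its size without passing (3.41, adjusted p 0.113) and Nat8f7 was at 1.66 (adjusted p 0.276). Genes of urinary proteins fell, with log2 changes of -4.71 (SE 0.78) for Mup18, -3.63 (SE 0.89) for Mup16 and -4.20 (SE 0.98) for Mup11. The mucin gene Muc1 changed by -6.81 (SE 0.58, adjusted p 1.54e-18) and Krt19 by -5.97 (SE 0.57), and Prr15l (-4.36), the adhesion gene Epcam (-4.32, SE 0.43), Smpd3 (-4.20), St14 (-3.60) and Cdh1 (-3.56) fell as well. Young male 2 decided most of these falls. Leaving out the same 7 libraries brought Muc1 to -1.04, Krt19 to -0.40 and Epcam to -0.30, left Cdh1 called at -2.18 (adjusted p 0.035), and brought the genes called from 955 to 86, of which 56 were among the 955. Without young male 2 alone, 257 genes passed.

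The same libraries carried the falls of muscle, matrix, fat storage and stress genes in males. Fabp4, a fatty acid carrier of adipocytes, changed by -3.45 log2 units (SE 0.44), the lipid droplet gene Cidec by -2.70 (SE 0.47), Srxn1, which repairs oxidised enzymes, by -2.04 (SE 0.24) and the mitochondrial carrier gene Ucp2 by -1.54 (SE 0.25), and without the 7 libraries they were at -0.13, 0.14, -0.07 and -0.91. Acta2 changed by -3.20 (SE 0.66), Des, the desmin of muscle and stellate cells, by -1.53 (SE 0.26), and Spp1, a secreted matrix protein, by -2.87 (SE 0.37). The immediate early genes Egr1 and Atf3 changed by -3.71 (SE 0.80) and -2.66 (SE 0.58), the small heat shock protein Hspb1 by -1.83 (SE 0.46), the cell cycle inhibitor Cdkn1a by -2.55 (SE 0.64) and the growth factor binding protein Igfbp1 by -3.15 (SE 0.82). Without the 7 libraries, Acta2 was at 0.26, Des at 0.16, Egr1 at 0.62, Atf3 at 1.29, Hspb1 at 0.76, Cdkn1a at 0.67 and Igfbp1 at 1.34, all of opposite sign. Cholangiocyte markers had a median of -2.53, and 8 of their 13 members fell both over all genes and adjusted over the list alone (adjusted p 2.48e-08, 0.0276 with an estimated correlation, 0.149 without the 7 libraries). Of 33 stellate cell and matrix genes, 17 fell over all genes and 20 adjusted over the list alone (median -0.971, adjusted p 0.00209). That list lost its call with an estimated correlation (adjusted p 0.937) and without the 7 libraries (adjusted p 0.42). Of 16 immediate early genes, 5 fell over all genes and 8 adjusted over the list alone, with a median of -0.88 and an adjusted p of 0.006, against 0.937 with an estimated correlation and 0.0783 without the 7 libraries. In 56 and 46 of 100 relabelings of young and old males, these last lists had a p as low as the real one.

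The effect of age differed between females and males for 557 genes, and the sign below is that of the female minus the male effect. Muc1 differed by 7.34 log2 units (SE 0.90, adjusted p 2.54e-09) and Cd24a, a surface protein of biliary cells, by 6.28 (SE 1.00). The acute-phase gene Saa2 differed by 6.77 (SE 2.02, adjusted p 0.0341), and Slco1a1, Cyp2b9 and Cyp2b13 by -4.04 (SE 0.94), -3.87 (SE 1.06) and -4.82 (SE 1.40). Without young male 2, 20 genes passed. Without all 7 libraries with a wide spread no gene passed by edgeR, where 2367 had passed an unadjusted 0.05 in all libraries and limma-trend had called 9. Muc1 was then at 1.43 and Cd24a at 1.56, while Slco1a1 (-3.72, adjusted p 0.464), Cyp2b9 (-3.76, adjusted p 0.511), Cyp2b13 (-4.63, adjusted p 0.569) and Saa2 (7.24, adjusted p 0.401) kept their size without passing.

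Females and males were compared to find the sex difference at each age, and it gave the most genes called. With cohort and site terms for each sex, 5157 genes passed in old and 1625 in young controls when averaged over cohorts and sites, and 1009 and 334 for the first cohort and site alone. In old controls, 2817 genes were higher in females and 2619 in males. Several of the genes that differed most were nearly silent in males or in females. Sult2a1 (ENSMUSG00000078798), a steroid sulfotransferase, was 14.26 log2 units higher in females (SE 0.44, adjusted p 4.03e-61), at 528 ± 191 CPM in 24 females against 0.0239 CPM in 24 males. Sult2a2 differed by 12.41, A1bg, a plasma glycoprotein, by 13.12 (SE 0.63), Cyp3a41b by 11.84 and Cyp2b9 by 5.64 (SE 0.51). Cyp4a12a, a fatty acid hydroxylase, was lower in females (log2 difference -12.82, SE 0.48, adjusted p 2.51e-53), at 0.084 against 609 CPM. Mup7 (-10.44), Mup12 (-9.42), Cyp2d9 (-6.41) and the complement regulator Susd4 (-5.64) were also lower in females. Where the CPM in a sex was near 0, the log2 difference depends on the added prior count. Reads of the Sult2a, Cyp3a, Cyp2b and Mup families can be divided among copies.

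Members of other lists with the lowest p in them differed by sex as well. The terminal complement genes C6, C8a, C8b and C9, which form the membrane attack complex, were lower in females by log2 differences of -3.71 (SE 0.22, adjusted p 3.68e-32), -2.66 (SE 0.25), -2.49 (SE 0.22) and -1.58 (SE 0.18). The oxysterol hydroxylase gene Cyp7b1 (-3.94, SE 0.26) and the heme synthesis gene Alas2 (-3.48, SE 0.22) were lower too. Acot3, a thioesterase of peroxisomes, was higher in females by 4.38 (SE 0.45), the lipoprotein receptor gene Vldlr by 3.32 (SE 0.33), the cyclin gene Ccnd1 by 2.60 (SE 0.23), the lysosomal gene Hexb by 2.25 (SE 0.15), the interferon-induced Gbp2 by 1.99 (SE 0.21) and the carbonyl reductase gene Cbr1 by 1.13 (SE 0.11).

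Immune genes also differed by sex in old mice. Of 17 markers of T and NK cells, 16 were higher in females and 1 lower, with Trbc2 at 1.87 (SE 0.28), Lck at 1.5 and Cd4 at -1.90 (SE 0.26). Adjusted over the list alone, the 17 markers divided in the same way, and the adjusted p was 6.47e-09 (0.308 with an estimated correlation). Kupffer cell markers were higher in females for 22 of 29 genes, and for 23 adjusted over the list alone, among them Vsig4 (1.15, SE 0.18), Cd5l (1.18) and Cd74 (1.17, SE 0.21), with an adjusted p of 1.19e-06 (0.585 with an estimated correlation). Of 24 sinusoidal endothelial markers, such as Plvap (0.53, SE 0.10), 18 were higher in females over all genes and 22 adjusted over the list alone, at an adjusted p of 8.07e-05 (0.585 with an estimated correlation). The chaperone Hyou1 (-0.69, SE 0.17) and the ligase Syvn1 (-0.86, SE 0.20) of the endoplasmic reticulum were lower in females, with 13 of 20 genes of that stress response lower over all genes, and 16 lower and 1 higher adjusted over the list alone (adjusted p 0.00248, 0.706 with an estimated correlation). Nqo1, a quinone reductase, was higher in females by 1.27 (SE 0.13, 15.9 against 6.64 CPM), the hormone precursor Agt by 0.68 (SE 0.09) and Cyp7a1, the first enzyme of bile acid synthesis, by 0.89 (SE 0.32), while Hspa1b was lower (-1.53, SE 0.48). Saa1 was higher by 3.42 (SE 0.81, adjusted p 0.000286), which fell to 1.36 (adjusted p 0.109) without the libraries of wide spread, of which female control 20 held 10800 CPM.

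In young controls, 1025 genes were higher in females and 1720 in males, from 6 libraries per sex. Sult2a1 differed by 12.67, Cyp2b9 by 9.51 (SE 1.21, adjusted p 3.29e-10), Cyp4a12a by -11.64 and Nqo1 by 1.49 (SE 0.27). Of 43 female-biased genes chosen in advance, 42 were higher in old females (median 4.78, adjusted p 1.73e-97, 1.34e-09 with an estimated correlation) and 38 in young females (median 5.33, 3.19e-09 with an estimated correlation). Male-biased genes were lower in females for 31 of 34 members at both ages, with medians of -4.04 and -4.36. The inducible heat shock gene Hspa1a differed by -5.92 (SE 1.29) in young mice, but by -1.27 without the young males 1 and 2 and the other libraries of wide spread, and the count of called genes then fell to 1301.

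Canagliflozin, an inhibitor of glucose transport in the kidney, was fed at 180 ppm from 7 months. Averaged over both sexes, 17 genes fell and 1 rose, and genes of fat synthesis were among those that fell. The fit held 14 treated mice and 48 old controls, 20 of them from the cohort of the treated mice. Pnpla3 (ENSMUSG00000041653), a lipid droplet protein switched on by feeding, fell by 3.43 log2 units (SE 0.65, adjusted p 0.00625). It was at 11.5 ± 9.54 CPM in 7 females against 90.7 ± 65.7 in 24 controls of all cohorts. In males it was at 1.11 ± 0.931 against 15 ± 12.9 CPM. Acaca, which makes malonyl-CoA for fatty acids, changed by -0.84 (SE 0.18, adjusted p 0.0181), and Gck, the glucose-phosphorylating enzyme of liver, by -0.82 (SE 0.17, adjusted p 0.0153). The glucose transporter Slc2a4 changed by -2.73 (SE 0.59), the receptor genes Chrna4 and Adgrv1 by -2.39 (SE 0.58) and -1.76 (SE 0.38), the protease Prss8 by -1.47 (SE 0.32), the chromatin organiser Satb1 by -1.39 (SE 0.31), Fam198a by -1.35 (SE 0.31) and Lrrc39 by -0.98 (SE 0.24). The gene that rose was Cyp2c69, a female-biased member of a family with divided reads, at 2.34 (SE 0.51, adjusted p 0.0181). As given below, its effect in females was far lower than in males, so this rise was not shared by the sexes. Pnpla3 and the genes from Slc2a4 to Lrrc39 lay below the control mean of their sex in all 14 treated libraries. Fasn, the fatty acid synthase, differed by -1.14 (SE 0.30, adjusted p 0.105), at 948 against 2060 CPM in females and 590 against 1720 CPM in males, Acacb by -1.01 (SE 0.25, adjusted p 0.0598) and the pyruvate kinase Pklr by -0.91 (SE 0.24, adjusted p 0.105).

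As a list, fatty acid and triglyceride synthesis was lower under canagliflozin with a median of -0.741. Over all genes 2 of its 21 members fell, and adjusted over the list alone 15 fell (adjusted p 7.31e-20, 0.0745 with an estimated correlation, 0.0161 with an estimated correlation without the libraries of wide spread). No other of 100 relabelings had a p as low. Glycolysis had a median of -0.133, with 1 of 18 genes lower over all genes and 4 adjusted over the list alone, and an adjusted p of 6.19e-05 (0.183 with an estimated correlation). Cell cycle genes had a median of -0.404 with no member called over all genes and 5 of 30 adjusted over the list alone (adjusted p 2.5e-06, 0.521 with an estimated correlation). The count of 18 genes ranged from 5 without male Cana 2 to 28 without male Cana 6. Without the libraries of wide spread, of which male Cana 7 was 1, 28 genes passed, 16 of them shared, and Pnpla5, a relative of Pnpla3 named after its value was seen, was at -4.28 (SE 0.81, adjusted p 0.00274).

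**Figure D1:**
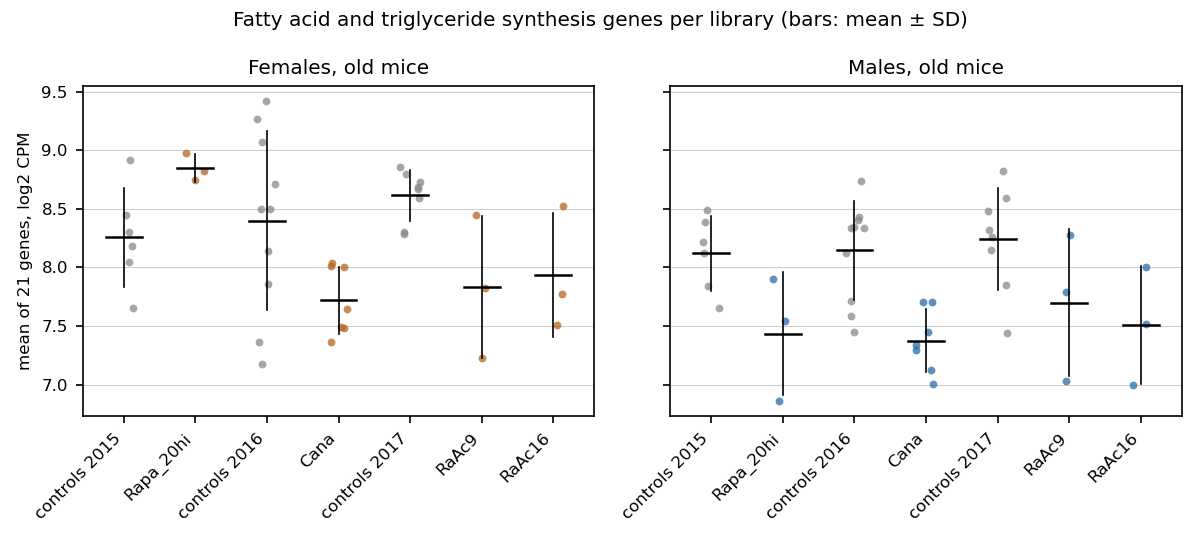
Mean log2 CPM of 21 genes of fatty acid and triglyceride synthesis (vertical axis) in old females and males, by treatment and by control cohort (horizontal axis), with a point per library and bars for the mean ± SD. Female Cana libraries lay between 7.37 and 8.04 against 7.17 to 9.42 in 24 controls of all cohorts, and male Cana libraries between 7.01 and 7.71 against 7.44 to 8.82.

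Within each sex, 7 libraries against 24 controls of all cohorts, with a cohort term, gave few calls for canagliflozin. In females, Rims4, a synaptic scaffold gene, fell by 4.00 log2 units (SE 0.71, adjusted p 0.000949), while Pnpla3 was at -3.12 (adjusted p 0.282, 0.007 by DESeq2) and the proliferation marker Mki67 at -1.73 (adjusted p 0.466). In males, the receptor gene Gprc5a rose by 1.90 (SE 0.42, adjusted p 0.035), Selenow, a selenoprotein, rose by 0.66 (SE 0.15, adjusted p 0.035), and Eif2ak4, a kinase that senses amino acid shortage and was named after its value was seen, changed by -0.47 (adjusted p 0.00192). Without the libraries of wide spread these males' values were 1.59, 0.38 and -0.39 (adjusted p 0.198, 0.516 and 0.107). In males, Pnpla3 was at -3.75 (adjusted p 0.136, 0.000208 by DESeq2) and Fasn at -1.35 (adjusted p 0.286). The fat synthesis list had medians of -0.778 in females and -0.704 in males, with adjusted p of 1.9e-11 and 3.2e-11, and with an estimated correlation 0.409 and 0.756. Adjusted over the list alone, 14 members fell in females and 13 in males. The response differed by sex for 2 genes, the paralogs Cyp2c69 (-5.04, SE 0.95, adjusted p 0.00705) and Cyp2c40 (-4.46, SE 0.88, adjusted p 0.00972), female minus male effect, and for none without male Cana 3. By limma-trend that count was 0, against 1090 genes at an unadjusted p of 0.05 by edgeR and 6 called by DESeq2.

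Rapamycin, an inhibitor of the growth kinase mTOR, was given with acarbose, which slows starch digestion. Feeding began at 9 months (RaAc9) or 16 months (RaAc16), with 3 treated mice per sex. The fit held 24 old controls per sex, and 16 over both sexes came from the cohort of the treated mice. Started at 9 months, 1 gene rose and 4 fell, and started at 16 months, 4 rose and 5 fell. Wfdc2, a secreted protease inhibitor, fell by 2.19 log2 units (SE 0.48, adjusted p 0.044) in RaAc9 and by 2.40 (SE 0.50, adjusted p 0.0296) in RaAc16, and Bin1, which bends membranes, by 0.73 (SE 0.15, adjusted p 0.013) and 0.69 (SE 0.15, adjusted p 0.0343). RaAc9 also raised Olig1 by 2.11 (SE 0.43) and lowered the amino acid transporter gene Slc7a4 (-1.06, SE 0.24) and Dennd2d (-0.77, SE 0.15). RaAc16 raised Msmo1, an enzyme of cholesterol synthesis, by 1.01 (SE 0.23, adjusted p 0.0362), Tpgs2 by 0.47 (SE 0.11) and Sumf1 by 0.33 (SE 0.07), and lowered Sult1c2 (-1.61, SE 0.34), the growth factor gene Vegfb (-0.82, SE 0.19) and Mroh1 (-0.32, SE 0.07). All 6 treated libraries lay on the same side of the control mean for each. Below the threshold, Msmo1 was at 0.82 in RaAc9 (adjusted p 0.147), Acacb at -1.12 in RaAc9 (adjusted p 0.22) and -1.17 in RaAc16 (adjusted p 0.238), Pnpla3 at -3.06 and Fdft1 at 0.64 in RaAc16 (adjusted p 0.238 and 0.227), and the cathepsin gene Ctsl at -0.60 in RaAc9 (adjusted p 0.0962).

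Fatty acid and triglyceride synthesis was lower in both combinations, with medians of -0.704 in RaAc9 and -0.644 in RaAc16 and adjusted p of 1.11e-11 and 1.75e-12. With an estimated correlation these were 0.352 and 0.548. No member passed over all genes by edgeR or limma-trend, DESeq2 called Pnpla3 in RaAc16 (-3.14, adjusted p 0.0157) and none in RaAc9, and adjusted over the list alone 2 of 21 fell in RaAc9 and 12 in RaAc16. Cholesterol synthesis had medians of 0.217 and 0.252, with 7 and 6 of 25 genes up adjusted over the list alone, and adjusted p of 1.91e-05 and 6.34e-08 (0.945 and 0.832 with an estimated correlation). Haemoglobin and erythroid genes had medians of -1.54 and -1.52. Among them, Hbb-bt was at -2.13 in RaAc9 (adjusted p 0.111, 0.00855 by DESeq2) and Hba-a2 at -1.71 in RaAc16 (adjusted p 0.283), 5 of 8 members fell in each adjusted over the list alone, and adjusted p were 1.91e-05 and 0.00163 (0.352 and 0.8 with an estimated correlation). The counts depended on the fit. RaAc9 gave 0 to 6 genes and RaAc16 0 to 1 when a replicate number was dropped from every group, 65 and 29 without the libraries of wide spread, 45 and 22 by DESeq2, and 327 and 300 with only the controls of their cohort. The folds moved less: without replicate 1, 2 or 3, Wfdc2 in RaAc16 was at -2.66, -2.04 and -2.66 and Bin1 at -0.84, -0.59 and -0.67. Among the genes called without the libraries of wide spread were Ulk1, a kinase that starts autophagy, at -0.71 in RaAc16, and the lysosomal genes Glb1 (-0.59), Gusb (-0.53) and Ctsl (-0.61) in RaAc9, named after their values were seen. No gene differed between RaAc9 and RaAc16 by edgeR, 348 passed an unadjusted p of 0.05, DESeq2 called 2 and limma-trend 0.

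With rapamycin at 42 ppm from 20 months (Rapa_20hi), 3 genes rose and 7 fell, and 3 of those that fell belong to the interferon response, which cells switch on against viruses. Oas1g and Oas3, sensors of double-stranded RNA, fell by 2.7 log2 units (SE 0.61, adjusted p 0.0403) and 2.27 (SE 0.52, adjusted p 0.046). H2-T24 changed by -1.45 (SE 0.33), Apol9b by -1.41 (SE 0.32), Tnfrsf14 by -0.96 (SE 0.22), the RNA sensor gene Ddx58 by -0.71 (SE 0.15) and Dennd2d by -0.69 (SE 0.16). Rala, a small GTPase, rose by 0.38 (SE 0.08), Rpf1, needed for ribosome assembly, by 0.36 (SE 0.08) and Tax1bp1, an autophagy receptor, by 0.23 (SE 0.05). Gbp3 (-1.76, adjusted p 0.0522), the peptide transporter gene Tap1 (-0.89, adjusted p 0.0798), the endothelial receptor gene Stab2 (-1.02, adjusted p 0.0798), the B cell genes Cd79a and Ms4a1 (-2.43 and -2.66, adjusted p 0.0798 and 0.123) and the T cell gene Cd3g (-1.66, adjusted p 0.114) did not pass by edgeR, while DESeq2 called all 6 (adjusted p of 0.00285 for Gbp3 to 0.0405 for Cd3g). The 32 interferon genes had a median of -1.06, with 3 lower over all genes by edgeR (11 by DESeq2) and 27 adjusted over the list alone, and an adjusted p of 4.86e-22 (0.269 with an estimated correlation). The same genes were lower than the same controls under MitoQ and minocycline (Min), a mitochondrial antioxidant and an antibiotic. Medians were -1.25 with MitoQ (28 of 32 lower adjusted over the list alone, adjusted p 2.13e-29, 0.0695 with an estimated correlation) and -0.812 with Min (17 lower adjusted over the list alone, adjusted p 1.57e-19, 0.144 with an estimated correlation). Of 100 labelings, the real one included, 13 for Rapa_20hi, 4 for MitoQ and 17 for Min gave this list a p as low as the real one. No member passed over all genes for MitoQ and Min by edgeR (4 and 0 by DESeq2, 0 and 0 by limma-trend), with Oas1g at -2.60 in MitoQ (adjusted p 0.139, 0.00248 by DESeq2) and at -2.32 in Min and Stat1 at -0.82 in Min (adjusted p 0.868 for both). Interferon response means (log2 CPM) in the C2015 controls were 4.05 ± 0.622 in 6 females and 3.44 ± 1.01 in 6 males, against 3.53 and 3.08 in the C2016 controls and 3.66 and 3.12 in those of C2017. Fatty acid and triglyceride synthesis had a median of -0.0192 in Rapa_20hi (adjusted p 0.739, 0.929 with an estimated correlation). Dropping any replicate number left no gene called for Rapa_20hi by edgeR (1721 at an unadjusted p of 0.05 in all libraries; 82 by DESeq2, 0 by limma-trend), and 77 passed without the libraries of wide spread. Without replicate 1, 2 or 3, Oas1g stayed at -2.89, -2.31 and -2.76 and Ddx58 at -0.79, -0.7 and -0.69.

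Male mice received 17-alpha-estradiol, an estrogen with weak feminising action, at 14.4 ppm. Started at 20 months, 27 genes rose and 1 fell, with acute-phase and female-biased genes at the top. Saa2 rose by 6.53 log2 units (SE 1.49, adjusted p 0.018), the iron-binding protein gene Lcn2 by 5.50 (SE 1.22), Orm2 by 4.34 (SE 1.01) and Serpina3n by 1.52 (SE 0.36). Sult1e1, an estrogen sulfotransferase, rose by 6.39 (SE 0.90, adjusted p 2.03e-07), Cyp2c69 by 5.90 (SE 0.81), the transcription factor gene Cux2 by 5.42 (SE 0.66, adjusted p 1.31e-09), the transporter gene Slc22a26 by 5.24 (SE 0.66) and Cyp3a44 by 3.50 (SE 0.55). Replicate 2 decided these values, with 53.2 CPM of Cux2 and 4070 CPM of Saa1. Without replicate 2 of all groups of 3, no gene passed by edgeR, where 725 passed an unadjusted 0.05 in all libraries and DESeq2 called 25 and limma-trend 1, and Saa2 was at -0.59, Lcn2 at -0.74, Orm2 at -0.47 and Slc22a26 at -0.16. Acute-phase genes had a median of 1.14 (5 of 26 up over all genes, 19 adjusted over the list alone, adjusted p 1.7e-15, 0.475 with an estimated correlation), and female-biased genes a median of 1.37 (8 of 43 up over all genes, 16 adjusted over the list alone, adjusted p 5.75e-09, 0.475 with an estimated correlation). Started at 16 months, no gene passed by edgeR, 558 did at an unadjusted p of 0.05, DESeq2 called 2 and limma-trend 0. Usp2, a clock-linked protease, was at 3.03 (adjusted p 0.547). Markers of T and NK cells had a median of 0.946 in Est_16 (Il2rb 1.12, adjusted p 1), with an adjusted p of 5.7e-08 for the list, 0.947 with an estimated correlation, and no member passing adjusted over the list alone. Slc22a26 differed between the starting ages by -6.85 (SE 1.37, adjusted p 0.0243), Est_16 minus Est_20, and was the only such gene by edgeR. It was at -0.99 (adjusted p 1) without replicate 2, and DESeq2 called 16 genes.

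1,3-butanediol (BD), a ketone precursor, was fed at 100000 ppm from 6 months, and 167 genes rose and 16 fell in the mean of the sexes. Scn8a rose by 3.56 log2 units, the epithelial gene Ly6d by 3.82, the desaturase gene Scd2 by 2.90, the fetal liver genes Gpc3 and Afp by 2.7 and 1.43 (Afp SE 0.27, adjusted p 0.000207), Apoa4 by 2.59 and Fam83a by 2.23. Slc26a4, Tmem266 and the ornithine enzyme gene Oat changed by -2.00, -1.53 and -1.35, and Igf1, the liver's main growth hormone target, by -0.50 (SE 0.13, adjusted p 0.0315). Male BD 1, a library of wide spread, had 172 CPM of Afp, 214 CPM of Tff3 and 345 CPM of Tspan8. Without replicate 1 the rises shrank, to 1.41 for Scn8a, 1.01 for Scd2, 0.22 for Gpc3 and -0.22 for Afp, while the falls stayed near their size without passing, at -2.33 for Slc26a4, -1.63 for Tmem266, -1.05 for Oat and -0.41 for Igf1. In males alone 939 genes rose and 152 fell, and in females none passed by edgeR, with 240 at an unadjusted p of 0.05. Without the libraries of wide spread 10 genes passed, 8 of them shared, and Mmp9, a matrix protease named after its value was seen, was among those left at 2.46 (adjusted p 0.00251). Genes of the pericentral zone, such as Cyp2e1 (-0.83, adjusted p 0.0839), had a median of -0.657 with 1 of 18 lower over all genes and 11 adjusted over the list alone, and an adjusted p of 6.4e-25, 0.00447 with an estimated correlation and 0.12 with an estimated correlation without the libraries of wide spread. Bile acid genes (median -0.32, adjusted p 3.72e-11) had an adjusted p of 0.0218 with an estimated correlation, lost at 0.12 without the libraries of wide spread, and adjusted over the list alone 5 of 21 fell. Urea cycle and amino acid genes (median -0.32, adjusted p 7.69e-14) had 5 of 28 lower adjusted over the list alone and 0.0808 as adjusted p with an estimated correlation. Of 13 liver tumor and fetal genes, 5 rose over all genes, and adjusted over the list alone 5 rose and 1 fell (median 1.23, adjusted p 0.0062, 0.206 with an estimated correlation, 0.414 without the libraries of wide spread).

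Nicotinamide riboside (NR), a precursor of NAD, raised 137 genes and lowered 9. Rpl37, a ribosomal protein gene, rose by 0.97, the inflammasome adaptor gene Pycard by 1.30, Oas1g by 1.97 and Ccdc107 by 0.70, while Rgs7bp changed by -2.91 and the histone chaperone gene Rbbp7 by -0.38. The calls came from females, with 1379 genes up and 337 down. Without replicate 3 of all groups of 3 no gene passed by edgeR (2497 at an unadjusted p of 0.05 in all libraries; DESeq2 156, limma-trend 16), with Pycard at -0.08 and Oas1g at -0.51. Ribosomal protein genes had a median of 0.293, with 6 of 44 higher over all genes and 13 adjusted over the list alone, and an adjusted p of 4.74e-05 (0.985 with an estimated correlation, 0.155 without the libraries of wide spread). Genes of NAD metabolism had a median of 0.0182 (adjusted p 0.957, 0.985 with an estimated correlation), and Nnmt, which methylates nicotinamide, was at 1.19 (adjusted p 0.29). Geranylgeranyl acetone (GGA), an inducer of heat shock proteins, raised 22 genes, among them Serpina3n by 1.38 (SE 0.26, adjusted p 0.00423), the signalling inhibitor Socs3 by 1.65, Kazn by 0.95, Rasip1 by 0.79 and the ribosome assembly gene Heatr1 by 0.63. Acute-phase genes had a median of 0.75 under GGA, with 2 of 26 up over all genes and 16 adjusted over the list alone, at an adjusted p of 2.64e-10 (0.701 with an estimated correlation). Without replicate 2, or without the libraries of wide spread, no gene passed by edgeR for GGA (1420 at an unadjusted p of 0.05 in all libraries; DESeq2 22, limma-trend 0). In GGA males 1430 genes rose and 294 fell.

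MIF098, an inhibitor of macrophage migration inhibitory factor, raised 6 genes. Ddit4, a brake on mTOR, rose by 1.70 log2 units (SE 0.30, adjusted p 0.00078), the neutrophil genes S100a8 and S100a9 by 3.09 (adjusted p 0.00832) and 3.01, and the clotting regulator Serpine1 by 3.06 (adjusted p 0.0377). Hilpda and Gprc5a, named after their values were seen, rose by 1.11 (adjusted p 0.013) and 2.35 (adjusted p 0.00733). Each of these rises was lost when a replicate number was dropped. Without replicate 1, S100a8 was at -0.06, S100a9 at 0.62, Serpine1 at 0.82 and Hilpda at 0.74 (adjusted p 0.405), and without replicate 2, Ddit4 was at 0.49 and Gprc5a at 0.86. Ribosomal protein genes had a median of 0.214 with MIF098 and none of 44 passed adjusted over the list alone (adjusted p 7.79e-11, 0.689 with an estimated correlation). PB125, a plant extract mixture meant to activate NRF2, raised Psat1, an enzyme of serine synthesis, by 2.88 (SE 0.54, adjusted p 0.00576), which was 0.78 without replicate 3. The other call was the Y-linked Kdm5d (1.70, adjusted p 0.0325), which rests on 0.342 CPM in female PB125 1 against 0 in females 2 and 3 and is no measure of a response. Asns, which makes asparagine, and Mthfd2, of folate metabolism, were at 2.77 (adjusted p 0.0567) and 1.67 (adjusted p 0.0652). Genes of the integrated stress response had a median of 0.23 with PB125, 1 of 20 up over all genes and 6 adjusted over the list alone, and an adjusted p of 0.000138 (0.383 with an estimated correlation). NRF2 targets had a median of -0.0785 (adjusted p 0.142, 0.745 with an estimated correlation), with Gsta1 at -1.39 (adjusted p 1). MitoQ raised Cela1, an elastase, by 2.29 (SE 0.35, adjusted p 2.18e-05) and the zinc transporter gene Slc39a5, outside the naming rule, by 2.09 (adjusted p 0.0372), which were 0.49 and 0.52 without replicate 2.

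Sulindac (Sul), an anti-inflammatory drug, raised 9 genes, all higher in old control females than in males, with Sult2a2 at 3.82, Sult2a1 at 3.61, Cyp2c69 at 3.86 (named after its value was seen) and Cux2 at 2.91. Syringaresinol (Syr), a plant lignan, raised Cux2 by 2.98 (SE 0.50, adjusted p 0.000224), and leucine (Leu) raised Sult2a1 by 2.72 (SE 0.51, adjusted p 0.00525). Each rested on a single male library. Without replicate 1, no gene passed for Sul or Syr by edgeR (349 and 626 at an unadjusted p of 0.05 in all libraries; DESeq2 9 and 3, limma-trend 0 for both), Sult2a2 in Sul was at -1.13, and Cux2 in Sul and Syr was at -0.40 and 0.68. Without replicate 2, Sult2a1 in Leu was at 0.41. Female-biased genes had a median of 1.15 in Sul, with 9 of 43 up over all genes and 20 adjusted over the list alone (adjusted p 4.92e-16, 0.0826 with an estimated correlation). Haemoglobin and erythroid genes had medians of -1.4 in Sul and -1.29 in Syr, with 6 of 8 lower in each adjusted over the list alone, and adjusted p of 1.08e-07 and 1.33e-05 (0.0826 and 0.465 with an estimated correlation). Hbb-bt was at -1.61 in Syr (adjusted p 1). Sul, Syr, RaAc9 and RaAc16 shared the C2017 controls.

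For 5 compounds no gene passed by edgeR in the mean of the sexes. At an unadjusted p of 0.05, 556 genes passed for 17-DMAG (DMAG), an HSP90 inhibitor, 715 for candesartan cilexetil (CC), 232 for captopril (Capt), 596 for Min and 756 for beta-guanidinopropionic acid (bGPA). DESeq2 called 2, 1, 0, 1 and 3 genes in that order, and limma-trend 0 for each. The chaperone genes Hspa8 and Hspb8 were at 0.35 and 0.30 with DMAG, and the stress hormone target Fkbp5 at 0.95 (adjusted p 1 for all). Heat shock genes as a list had a median of 0.0864 (adjusted p 0.0984, 0.931 with an estimated correlation). For the blockers of the renin-angiotensin system, Ace2 was at -0.98 (adjusted p 0.889) and Agt at 0.12 (adjusted p 0.913) with CC, and Mas1 at -2.69 and Agt at 0.30 (adjusted p 1 for both) with Capt. The 8 genes of that system had medians of -0.116 and -0.0033, adjusted p of 0.283 and 0.435, and with an estimated correlation 0.829 and 0.925. With bGPA, which lowers creatine, the stress chaperone genes Herpud1 and Dnajc3 were at 0.83 (adjusted p 0.842) and 0.36 (adjusted p 0.758), and their list had a median of 0.357 with an adjusted p of 3.59e-11 (0.341 with an estimated correlation) and no member passing adjusted over the list alone. B and plasma cell markers had a median of -1.3 under bGPA, Pou2af1 was at -2.77 (adjusted p 0.387), and 11 of 23 were lower adjusted over the list alone (adjusted p 1.68e-07, 0.341 with an estimated correlation).

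The effects of the compounds were compared across all genes, which are not independent replicates, against control sets that did not overlap. RaAc9 and RaAc16 correlated with Pearson's r 0.492 and Spearman's rho 0.449, RaAc9 and Rapa_20hi with r 0.445 and rho 0.485, and RaAc16 and Rapa_20hi with r 0.333 and rho 0.387. Of 100 regroupings of the libraries, 0, 0 and 2 had an r as large, and the middle 95% of regroupings reached up to 0.453, 0.334 and 0.327. Without replicate 1 these r were 0.354, 0.312 and 0.118, and without replicate 2 they were 0.362, 0.364 and 0.222. Without replicate 3 they were 0.525, 0.412 and 0.382, so r depended on the replicate left out. The regroupings redrew the first compound of each pair and its controls with all libraries. No range was made for the fits without a replicate, so they cannot be judged against it. Cana and RaAc16 had r 0.305 and rho 0.233 (2 of 100 as large, the middle 95% up to 0.298, and 0.219, 0.221 and 0.342 without replicate 1, 2 or 3), Cana and RaAc9 r 0.152 and rho 0.0744 (20 of 100), and Cana and Rapa_20hi r -0.0092 and rho 0.046 (97 of 100). The starting ages of 17-alpha-estradiol had r 0.0711 and rho 0.085 (51 of 100). With the odd and even controls swapped, RaAc9 and RaAc16 had r 0.306 in place of 0.492, and no regroupings were made for that split. Of 16 genes fixed in advance, among them Fgf21, Pck1, Hmgcs2 and Bdh1, 320 values over 20 treatments gave 1 call, that of Igf1 in BD.

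A score of 52 genes that rose and 53 that fell with age, chosen in the young controls and the odd-numbered old ones, asked whether a compound moved old liver towards the young state. Male-high genes of the sex score below were among those that fell (Mup7, Mup1, Cyp2d9, Ugt2b1) and those that rose (Plekhb1, Osbpl3, Gpc1). A loss of male-high genes can therefore move the age score. Males Sul 1, Est_20 2, Syr 1 and BD 1, low in Cyp4a12a, had age scores of 0.61, 0.607, -0.0751 and -0.0218. Even-numbered old controls scored -0.0432 ± 0.484 in 12 females and -0.593 ± 0.451 in 12 males, and young mice, which had served to choose the genes, -1.877 ± 0.477 and -2.809 ± 0.476. Cana was lower than its controls by 0.492 (two-sided permutation p 0.00626, adjusted over 20 treatments 0.125), by 0.212 without the libraries of wide spread (p 0.0533, adjusted 0.312) and by 0.297 when the even-numbered controls chose the genes (p 0.0766, adjusted 0.511), and BD was higher by 0.553 (exact permutation p 0.0776, adjusted 0.477). No treatment passed.

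**Figure D2:**
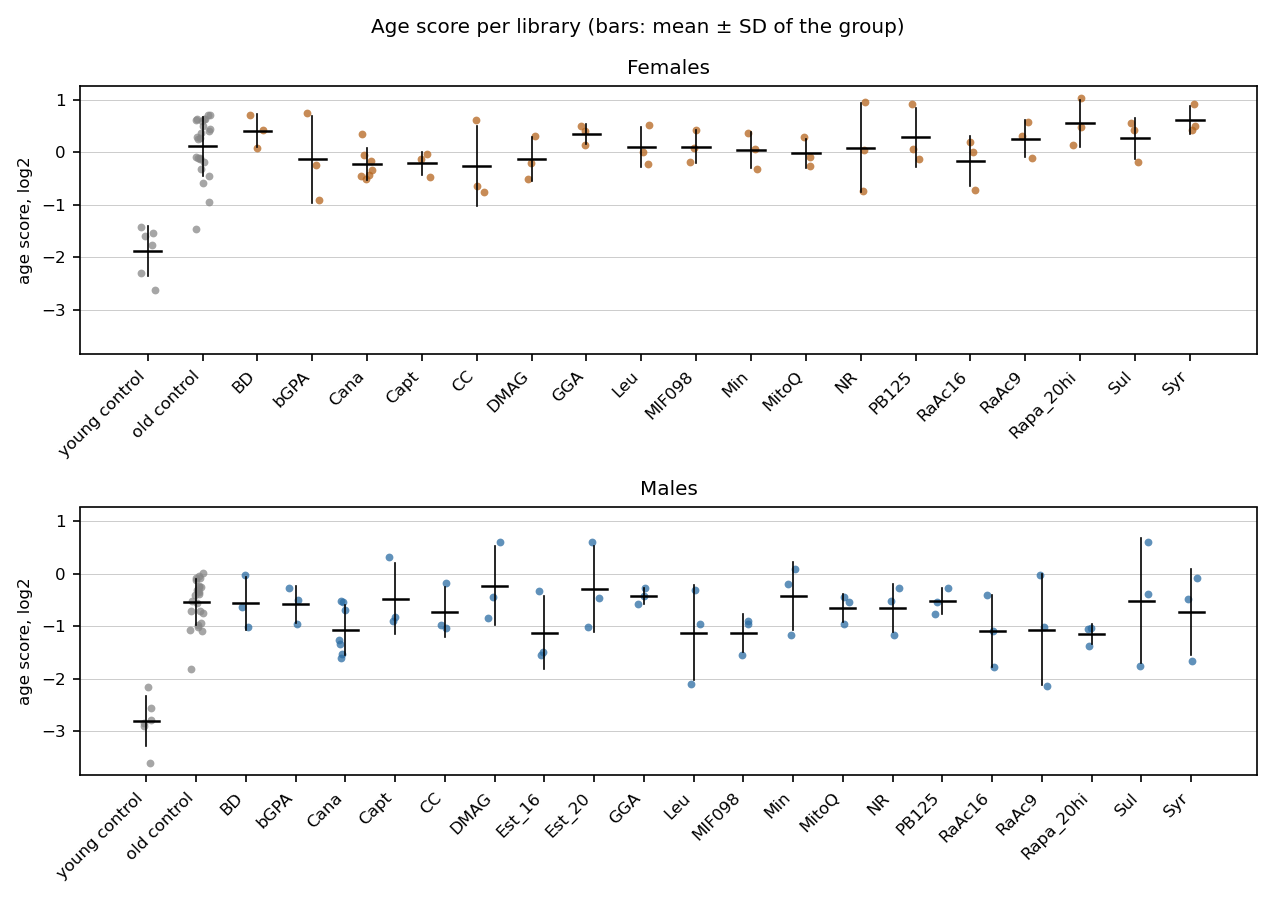
Age score in log2 units (vertical axis) of every library by group (horizontal axis), females above and males below, with a point per library and bars for the mean ± SD. Young controls lay at -1.877 in females and -2.809 in males, below the mean of every old group.

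A score of 200 female-high minus 200 male-high autosomal genes, chosen in the odd-numbered old controls, asked whether a compound moved the liver towards the other sex. Even-numbered old controls scored 1.266 ± 0.365 in 12 females and -3.26 ± 0.499 in 12 males. None of 38 treated groups passed, with adjusted p of at least 0.962. Est_20 was higher than its controls by 0.792 (two-sided exact permutation p 0.464) and Est_16 lower (difference -0.195, exact p 0.607). With 3 treated and 4 control libraries the smallest p possible was 0.0286, and the groups of the C2015 cohort could not go below 0.1. In 4 male libraries the score was at or above -1.05. This limit is the midpoint between the highest male and the lowest female even-numbered old control (-2.48 and 0.377). The scores were 0.238 in Sul 1, -0.553 in Est_20 2, -0.681 in Syr 1 and -1.05 in BD 1, where old male controls ranged from -4.03 to -2.48. BD 1 lay almost on the limit, so its place among the 4 depends on how the limit is set.

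**Figure D3:**
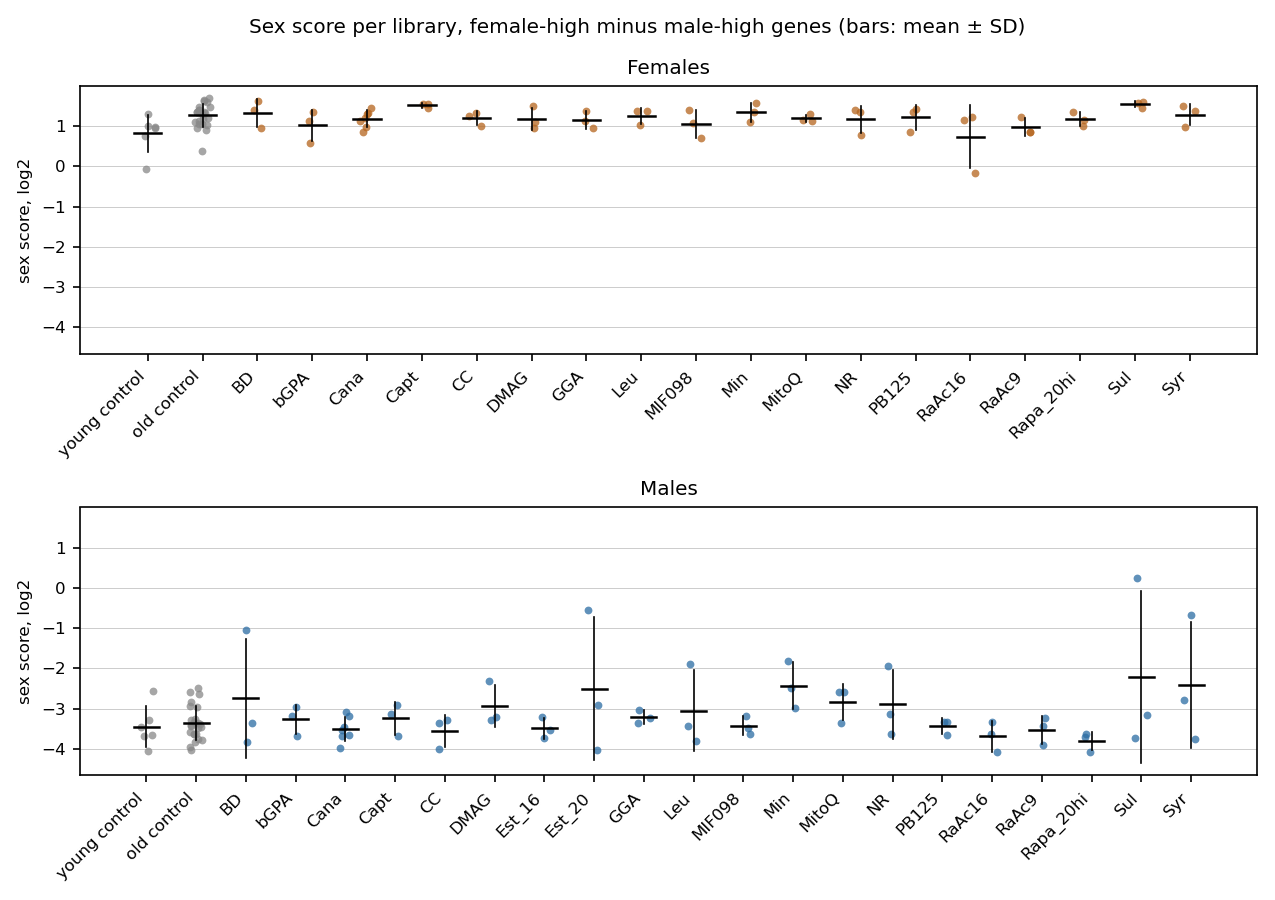
Sex score in log2 units (vertical axis) of every library by group (horizontal axis), females above and males below, with a point per library and bars for the mean ± SD. Male libraries Sul 1 (0.238), Est_20 2 (-0.553), Syr 1 (-0.681) and BD 1 (-1.05) lay above the highest old male control at -2.48.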

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

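The tests of biliary tissue, of the male libraries with a female pattern and of single libraries behind BD, GGA and NR were chosen after these results had been seen, and the redrawn labels were planned earlier.

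Young male 2 stood far above the other 5 young males in genes of bile duct and smooth muscle: its log2 CPM was 8.85 for Krt19 (others -0.211 to 2.31), 8.56 for Muc1 (-0.391 to 0.656), 7.11 for Smpd3 (0.932 to 2.68), 5.32 for Prr15l (-1.51 to 0.25), 4.6 for St14 (-1.2 to -0.57), 7.38 for Acta2 (-0.259 to 2.44) and 5.63 for Des (1.56 to 2.31), and its mean over stellate cell and matrix genes was 5.3 (2.67 to 3.63). Of 25 cholangiocyte, stellate cell and matrix genes called lower in old males, 3 were still called without it: Epcam at -2.15 (adjusted p 0.000149), Spp1 at -1.4 (adjusted p 0.00992) and Cdh1 at -3.02 (adjusted p 0.000511). Biliary wall tissue in 1 of the 6 young male libraries fits the loss of most of these calls. A first test that counted members of the cholangiocyte list below -1 had moved only from 7 to 6 of 13. Young male 1 also had more Epcam and Krt7 (12.6 and 2.64 CPM) than any old male control (at most 1.33 and 1.66 CPM). Young male 2 may therefore not be the only library affected. By edgeR without all 7 outlying libraries, Epcam was at -0.30 (adjusted p 0.816) and Spp1 at -0.66 (adjusted p 0.394). In young male 2, cholangiocyte and stellate markers were raised by 2.16 and 2.51, while Kupffer and endothelial markers were at 0.336 and -0.44. The gap of 1.82 argues against a lower share of hepatocytes as the sole cause, under a limit of 1 set after the values were seen. The 13 cholangiocyte markers varied widely (median absolute deviation 2.97). Added biliary tissue would itself lower the share of hepatocytes, so the test cannot exclude a lower share. Whether such tissue was dissected with the liver or grew in it may not be told from counts. Falls lost without young male 2, or without all 7 outlying libraries, are therefore no evidence of ageing. Cdh1 still passed by edgeR without all 7 (-2.18, adjusted p 0.035).

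Male libraries Sul 1, Est_20 2, Syr 1 and BD 1 had sex scores of 0.238, -0.553, -0.681 and -1.05, with Cyp4a12a at 0.0664, 3.42, 18.7 and 15.9 CPM against 417 to 830 CPM in old male controls, and Cyp2b9 at 547, 233, 497 and 200 CPM against at most 185 CPM, but the pattern was partial: Sult2a1 was at 10.6 CPM in Sul 1 and at 0.187, 0.0583 and 0.296 CPM in the others (mean of old females 528 CPM), and in BD 1, which mainly lost male genes, Cux2 (0.474 CPM) was within the control range of 0.0559 to 0.843 CPM. A mislabelled female library is excluded by a highest Xist of 0.531 CPM, where the lowest female had 161 CPM. RNA of a female liver mixed in is excluded too, since Xist was at most 0.1% of the female mean, while female-biased genes reached 47.7%, 27.1%, 14.2% and 1.24% of it. A shared treatment does not explain them, as the highest score among the other male libraries of these compounds was -2.8. With the midpoint of -1.05 as limit all 4 came from JL (4 of 20 treated males there, 0 of 24 at UM and 0 of 20 at UT), but Min 1 (JL, -1.806), Leu 2 (UM, -1.903), NR 3 (UT, -1.938) and DMAG 1 (JL, -2.322) also lay above the highest old male control (-2.48), so the tally by site depends on that limit, and a loss of the male pattern of growth hormone release in single animals could produce such livers but was not measured.

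Most calls for BD, GGA and NR were lost without the outlying libraries, 1 of which was in each treatment, male BD 1, male GGA 2 and female NR 3. Without the outlying libraries, 183 genes for BD became 10, which at 5.46% was the highest share left, 22 for GGA became none and 146 for NR became 1 (0.685%). Lower depth is excluded, as in 0 of these treatments did the outlying library have the lowest total of its group (17.0 M against 16.2 M, 20.8 M against 14.0 M and 33.3 M against 16.2 M counts). High Saa1 in male GGA 2 (15500 CPM) and female NR 3 (4200 CPM), and Afp of 172 CPM in male BD 1, may reflect inflammation or a liver tumour in single old animals, and 1 outlying library in each treatment fits the value of 5.46%.

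Igfbp1 was at 9.65 log2 CPM in young male 1, where the other young males ranged from 1.83 to 4.58. Srxn1 was at 10.2 log2 CPM in the same library (others 5.04 to 5.83). Sult2a1 was at 6.42 log2 CPM in young female 3 (others 8.22 to 9.18), the library without which 1 gene was called for age in females. These were among 11 of 116 values screened in 4 groups, and chance alone passes about 1 in 20. The screened genes and lists were those reported for comparisons of these same libraries. The 11 of 116 can therefore not be set against that share.

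The effect differed between females and males for 557 genes with age, 185 with BD, 483 with GGA, 198 with NR, 7 with Sul, 2 with Cana and 1 each with Leu, PB125 and Syr. Without the outlying libraries the first 4 of these counts became 0, 6, 0 and 0. The genes for Sul were led by Sult2a3 (-7.73) and Sult2a2 (-7.48), those for Leu, PB125 and Syr were Sult2a1 (-5.11), Kdm5d (3.89) and Cux2 (-6.13), and the value of the Y-linked Kdm5d rests on 0.342 CPM in female PB125 1 against 0 in females 2 and 3.

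Labels were redrawn 100 times, the real grouping included, and genes were counted by limma-trend. Redrawing was within sex and cohort, and for the comparisons of sex within cohort and site. The shares were not adjusted for the number of comparisons, and the counts are not those of edgeR. A rarely reached count shows no effect of treatment or age where single libraries carry it. Without the outlying libraries, edgeR called 10 genes for BD and 0 for age by sex. The real grouping alone reached its count for age in females (27, highest other 1), age by sex (9, 2), sex in old controls (5340, 1191), sex in young controls (2250, 1155), BD (72, 27), RaAc16 (9, 1) and RaAc9 (13, 1), each in 1 of 100. Cana reached 4 in 2 of 100 (highest other 57) and Cana in females 1 in 3 of 100 (highest other 1). Chance could not be excluded for age in males (268 in 6 of 100, highest other 735), NR (16 in 17 of 100, highest other 1632), Est_20 (1 in 25 of 100, highest other 81) and Cana in males (1 in 10 of 100, highest other 8). It was also not excluded where limma-trend called 0 genes and so 100 of 100 reached the count: the highest other was 2 for DMAG, 17 for CC, 0 for Capt, 1385 for GGA, 1 for Rapa_20hi, 2 for Leu, 21 for MIF098, 15 for Min, 50 for MitoQ, 2 for PB125, 1 for Sul, 3 for Syr, 12 for bGPA, 162 for Est_16, 2 for Cana by sex and 0 for RaAc9 against RaAc16. Est_16 against Est_20 had only 10 possible groupings (0 genes, 10 of 10 as many, highest other 37), which is too few to tell. Groupings that called several times the real count, as for age in males, Cana, GGA and NR, point to structure among the libraries such as single outlying ones.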

How the results depend on the processing

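The alternatives and the libraries left out were set before the fit, except for the fit without outlying libraries, chosen after the residuals had been seen. All counts are genes at an adjusted p below 0.05.

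Normalising with RLE factors or using edgeR's robust option moved none of 30 counts across the limits used for a change. Of the named gene values, 17 became stronger and 4 weaker with DESeq2 and the rest kept their side of the threshold, as did 199 without cohort and site terms (5 stronger, 16 weaker) and 217 with RLE factors (3 weaker). Leaving out replicate 1, 2 or 3 kept 170, 167 and 183, with 43, 48 and 31 weaker and 4, 4 and 2 reversed. Leaving out the outlying libraries kept 165, with 10 stronger, 43 weaker and 10 reversed. A filter without any expression limit was void, because every deposited gene passed the main filter.

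DESeq2 called more genes for most compounds: 54 for age in females, 45 for Cana, 19 for Cana in females, 10 for Cana in males, 6 for Cana by sex, 45 for RaAc9, 22 for RaAc16, 82 for Rapa_20hi, 12 for MitoQ, 16 for Est_16 against Est_20, 3 for Syr and bGPA, 2 for DMAG, Est_16 and RaAc9 against RaAc16, and 1 for CC and Min. The cause was not tested.

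Limma-trend called more genes for age in females (27) and RaAc9 (13) and fewer for most others, at 268 for age in males, 9 for age by sex, 72 for BD, 16 for NR, 4 for Cana, 1 for Cana in females, Cana in males and Est_20, and 0 for Cana by sex, GGA, Leu, MIF098, MitoQ, PB125, Rapa_20hi, Sul, Syr and Est_16 against Est_20. The cause was not tested.

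Without cohort and site terms, 51 genes passed for age in females, 92 for Cana, 22 for Cana in males, 50 for RaAc9, 39 for Rapa_20hi, 546 for NR, 73 for GGA, 61 for Est_20, 6 for Est_16, 14 for Sul, 12 for bGPA, 11 for MIF098, 4 for MitoQ and 2 for Leu. With cohort and site terms for each sex, 1009 passed for sex in old controls and 334 for sex in young controls. By construction these counts hold for the first cohort and site only, and averaged over cohorts and sites, chosen after seeing the data, they were 5157 and 1625. In the same fit 225 passed for age by sex, 642 for age in males, 11 for age in females, 11 for Est_20, 9 for Cana in males, 2 for Leu, 1 for Cana by sex, 1 for PB125 and 0 for Rapa_20hi and Est_16 against Est_20. The cause of the other changes was not tested.

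With only the libraries of a comparison and the controls of its cohort, which means fewer samples, 33 genes passed for age in females, 109 for age in males, 1423 for sex in young controls, 300 for RaAc16, 327 for RaAc9, 52 for Cana, 6 for Rapa_20hi, 2 for BD, 1 for Cana in males and 0 for Cana in females, Cana by sex, Est_20, Est_16 against Est_20, GGA, Leu, MIF098, MitoQ, NR, PB125, Sul and Syr. The stricter filter, which tests fewer genes, left 3 for Cana in males, 3 for MIF098, 1 for MitoQ and 0 for PB125. Among genes of at least 5 CPM, the correlation of effects was 0.391 for Cana and RaAc16 and 0.598 for RaAc9 and RaAc16.

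A replicate block, added to the model although replicate numbers do not pair animals, gave 461 genes for Cana, 681 for Cana in females, 44 for Cana in males, 4 for age in females, 44 for age in males, 172 for age by sex, 12 for Est_16 and for Est_20, 3 for RaAc16, 2 for BD, 1 for MitoQ and PB125 and 0 for Cana by sex, Est_16 against Est_20, GGA, Leu, MIF098, NR, RaAc9, Rapa_20hi, Sul and Syr. Numbers above 3 occur only in Cana and controls, so that the block takes part of these groups' means. Sex in old and young controls stayed at 5348 and 2515. Deviations from the group means correlated by 0.0491 between libraries of the same number, -0.0239 between other numbers and 0.0735 within a site, and 76 of 108 libraries were closest to their own number. Numbers mostly followed site: the mean was -0.0459 for the same number at other sites and 0.057 for other numbers at the same site, and 0.01 and -0.0259 once cohort and site were removed.

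Without the outlying libraries, 31 genes passed for age in females, 86 for age in males, 0 for age by sex, 1301 for sex in young controls, 10 for BD, 28 for Cana, 5 for Cana in females, 2 for Cana in males, 5 for Est_16, 75 for Est_20, 0 for GGA, 26 for MIF098, 1 for NR, 6 for PB125, 29 for RaAc16, 65 for RaAc9 and 77 for Rapa_20hi. The correlation of Cana and Rapa_20hi was -0.114. Cholangiocyte markers in ageing males had an adjusted p of 0.149, and tumor and fetal genes in BD 0.414. The direction reversed for immediate early genes (0.0783) and stellate cell genes (0.42) in ageing males and for ribosomal proteins in NR (0.155).

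In ageing males without the outlying libraries, Acta2 was at 0.26, Des at 0.16, Egr1 at 0.62, Atf3 at 1.29, Hspb1 at 0.76, Cdkn1a at 0.67, Cidec at 0.14 and Igfbp1 at 1.34, against falls with them. Afp in BD was at -0.28 and Rpl37 in NR at -0.02. The removal of single libraries by construction is the cause.

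With an estimated correlation in camera, most list calls were lost, because the estimate was above the preset value. The adjusted p for ageing females became 0.236 for B and plasma cells and 0.355 for bile acid, male-biased and nuclear oxidative phosphorylation genes, and for ageing males 0.937 for immediate early and stellate genes. For sex in old controls it became 0.585 for Kupffer and sinusoidal markers, 0.308 for T and NK cells and 0.706 for the endoplasmic reticulum list. Fatty acid synthesis became 0.0745 in Cana, 0.409 in Cana females, 0.756 in Cana males, 0.548 in RaAc16 and 0.352 in RaAc9, and in Cana cell cycle became 0.521 and glycolysis 0.183. Cholesterol became 0.832 in RaAc16 and 0.945 in RaAc9. Haemoglobin genes became 0.8 in RaAc16, 0.352 in RaAc9, 0.0826 in Sul and 0.465 in Syr. Interferon genes became 0.144 in Min, 0.0695 in MitoQ and 0.269 in Rapa_20hi. Acute-phase genes became 0.475 in Est_20 and 0.701 in GGA, female-biased genes 0.475 in Est_20 and 0.0826 in Sul, and T and NK cells 0.947 in Est_16. Ribosomal proteins became 0.689 in MIF098 and 0.985 in NR, B and plasma cells and the endoplasmic reticulum list 0.341 in bGPA, tumor and fetal genes 0.206 and urea cycle genes 0.0808 in BD, and the integrated stress response 0.383 in PB125. With redrawn labels, camera with the preset correlation called a median of 10 to 16 of 48 lists. As many as with the real labels were called in 6 of 100 for BD (22 lists), 7 for bGPA (23), 9 for Syr (17), 12 for age by sex (21), 74 for Cana (12) and up to 95 for NR (8).

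For single lists, the number of 100 labelings with a p as low as the real one, itself included, was 1 for male-biased and B cell genes, 3 for bile acid and 7 for nuclear oxidative phosphorylation genes in ageing females, and 4 for cholangiocyte markers in ageing males. For sex in old controls it was 9 for T and NK cells, 15 for Kupffer, 22 for sinusoidal and 28 for endoplasmic reticulum genes. Fatty acid synthesis had 1 in Cana, RaAc9, RaAc16 and Cana males and 9 in Cana females, cholesterol 9 in RaAc9 and 4 in RaAc16, and haemoglobin genes 5 in RaAc9, 8 in RaAc16, 3 in Sul and 9 in Syr. Female-biased genes had 15 in Est_20 and in Sul, acute-phase genes 2 in Est_20 and 9 in GGA, ribosomal proteins 24 in NR, and in BD tumor and fetal genes had 18 and pericentral genes 3.

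Leaving out single libraries or replicate numbers gave ranges of 1 to 41 genes for age in females, 257 to 1267 for age in males, 20 to 905 for age by sex, 5447 to 5655 for sex in old controls, 1761 to 3083 for sex in young controls, 5 to 28 for Cana, 1 to 6 for Cana in females, 1 to 9 for Cana in males, 0 to 2 for Cana by sex, 0 to 6 for RaAc9, 0 to 1 for RaAc16, 1 to 463 for BD, 0 to 160 for GGA, 0 to 1391 for NR, 0 to 3 for Leu, 0 to 11 for MIF098, 0 to 2 for MitoQ, 1 to 3 for PB125, 0 to 11 for Sul, 0 to 1 for Syr, 0 to 4 for bGPA, 0 to 8 for Est_16, 0 to 81 for Est_20 and 0 to 5 for Est_16 against Est_20. Rapa_20hi lost all its calls each time, and the other compounds stayed without one.

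Leaving out a replicate number reversed 10 gene values. Ranges were -0.59 to 8.5 for Saa2, -0.74 to 6.93 for Lcn2, -0.47 to 5.38 for Orm2 and -0.16 to 5.87 for Slc22a26 in Est_20, -0.22 to 1.73 for Afp in BD, -0.08 to 1.64 for Pycard and -0.51 to 2.73 for Oas1g in NR, -0.06 to 4.09 for S100a8 in MIF098, and -1.13 to 4.07 for Sult2a2 and -0.40 to 3.44 for Cux2 in Sul. A sign change was counted as a reversal only where the value passed in either setting. Of 1548 gene values 23 changed sign, most of them being the reversals above, and 13 of 160 age scores and 41 of 266 sex scores changed sign without passing. No alternative brought a score past the threshold. Age scores with up to 100 or 500 genes per direction used the same 52 and 53 genes as the main score, so they could not differ from it. Sex scores of groups of 3, and age scores of the C2015 compounds, Est_16 and Est_20, had too few arrangements for a low adjusted p. Their not passing therefore shows no stability. Genes under the deposited floor of 10 counts in 37 libraries could not be tested at this depth. For RaAc9, 75 of 100 simulated changes by a factor of 2 were recovered in counts without outlying libraries, and smaller changes were not simulated.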

Other observations

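The fit without the outlying libraries called some genes in several treatments. Genes in this paragraph that were not named above were chosen after the values were seen. RaAc9 and RaAc16 both raised Hnrnpab, an RNA-binding protein gene, by 0.32 and 0.34 log2 units, beside Msmo1 and Olig1, and both lowered Fbh1, a DNA helicase gene, beside Bin1, Sult1c2, Vegfb and Wfdc2. These treatments shared the C2017 controls, so the 3 and 5 shared calls are not evidence of a shared effect. RaAc9 and Rapa_20hi shared a rise of Pkdcc, a secreted kinase gene (0.60 and 0.58), and falls of Dennd2d and Tstd3. RaAc16 shared no call with Rapa_20hi, and Cana none with RaAc9, RaAc16 or Rapa_20hi. With so few calls, the overlap from unrelated lists (product of both counts over the genes tested) was at most 0.1 for these pairs. The absence of shared calls therefore shows no difference between the treatments. In Rapa_20hi, the interferon genes Ifi44 (-2.37), Usp18 (-1.73), Rtp4 (-1.41) and Parp9 (-0.48) were lower than in controls. So were the hexosamine gene Gnpda1 (-1.02) and Ppargc1a, a regulator of mitochondria (-0.82). Interferon genes as a list were also lower under MitoQ and Min against the same controls. For Rapa_20hi, 13 of 100 labelings gave that list a camera p as low, so an effect of the drug on these genes is not shown. Cana changed Mogat2, which makes diglycerides, by -1.8, the lipoprotein gene Apoa4 by -1.25, the desaturase gene Fads1 by -0.44, the mitochondrial import gene Samm50 by -0.33 and Ttc39b, a regulator of cholesterol export, by 0.67. None of these Cana genes was called in RaAc9 or RaAc16. There Mogat2 was at -1.24 and -0.27, Apoa4 at -0.51 and -0.68, Fads1 at -0.47 and -0.47, and Samm50 at -0.28 and -0.19. Only Ttc39b had the other sign (-0.33 and -0.15). Est_16 raised Cntnap1 by 1.87 and the lipoprotein gene Apoc2 by 1.5 (adjusted p 0.0219).

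Single sexes gave calls of their own, and the genes named here were chosen after the values were seen. In 3 PB125 females, Psat1, also called in the mean of the sexes and there at 0.78 without replicate 3, was up by 4.99 (adjusted p 8.42e-10), the growth inhibitor gene Cgref1 by 3.12 and the hormone gene Fgf21 by 2.76 (adjusted p 0.0475). In DMAG males, Clca3a1 rose by 2.38 (adjusted p 0.00483) and the antioxidant gene Sod3 by 1.28 (adjusted p 0.02), in Min males Cntnap1 by 2.38 (adjusted p 0.00174), in Capt females the antibody gene Ighg2c by 4.76 (adjusted p 0.00205) and in bGPA females Isyna1, which makes inositol, by 3.49 (adjusted p 0.0375). No difference between the sexes passed for any of these genes. Without the outlying libraries, old female control 20 among them, MIF098 females had 1004 calls (8 with all libraries, 2457 at an unadjusted p of 0.05). CC females then had 220 and RaAc9 females 36, where with all libraries edgeR called none and 1810 and 1251 passed an unadjusted 0.05.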
